A study of Homo sapiens with 82 samples.

How the data were processed

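The series holds RNA-seq, Ribo-seq, GTI-seq and Sel-TCP-seq libraries of HEK293T cells grown in DMEM with 10% FBS, per the labels' protocols. Sodium arsenite was given at 40 µM for 60 min and LTM at 50 µM for 30 min, CHX was present at 100 µg/ml in the lysis buffer, and footprints made with RNase I were taken from 17 to 34 nt, per the labels' protocols. Reads were trimmed with cutadapt, aligned with STAR and counted with featureCounts, per the submitters' processing notes; the versions are not given in the sources used here. The deposited table holds raw read counts for 226882 transcript rows in 82 columns, which are whole numbers, with Ensembl transcript identifiers and coordinates on GRCh38 (the notes name GRCh38.p13 and hg38). What follows was computed here.

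Each transcript row was named by the overlap of its coordinates with RefSeq genes on GRCh38.p14. At least 50% of the joint span had to be shared, or 20% where at least 90% of the transcript lay within the gene. In total 17701 transcripts start and end exactly where a RefSeq gene does (8904 protein-coding genes). This named 159783 transcripts of 45751 genes, 19369 of 20050 protein-coding ones among them, and 161 copies on the Y pseudoautosomal regions were left out. The design had planned to sum rows to genes. Overlapping transcript rows (a median of 4 per protein-coding gene) hold the same reads more than once, so 1 transcript was kept per gene: the shortest that held at least 95% of the gene's highest transcript count in each assay, or otherwise the one with the highest mean share. The sum per gene is an alternative chosen after the data were seen. Transcripts whose exons hold a small RNA gene were set aside (186 genes). Genes that overlap another gene cannot be told apart without strand and those with strong overlap are not named, and reads shared with near-identical copies, as between ribosomal protein genes or histones and their copies, leave those genes uncertain.

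Of the 82 columns 78 entered the fits. The other 4, RNA-seq of arsenite-treated eIF2A KO cells, equal the columns of the untreated cells in each row and were not used. The labels give the WT Ribo-seq samples an RNA-seq protocol entry; they were treated as Ribo-seq, as their titles and columns say. The 4 untreated WT RNA-seq columns carry 2 names, each used for 2 columns, and are called here the first-listed and the second-listed pair. In column order the first-listed pair stands beside the knock-in RNA-seq libraries, and the second-listed columns beside the untreated KO RNA-seq libraries. Which experiment each pair belongs to is not stated. Fits of the knockouts pooled all 4 columns, so a difference between the pairs enters their fold changes and counts. The knock-in cells are described by the column headers as also carrying tagged eIF4E. Groups were taken from the labels, with each knockout line and each siRNA as its own group, and no sample was removed.

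Counts were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1, data.table version 1.17.8): filterByExpr with a minimum count of 10, TMM factors, robust quasi-likelihood F tests, and Benjamini-Hochberg adjustment at 0.05 over the genes of each comparison. Each knockout or siRNA effect is the mean of its lines or siRNAs minus the control. Translational efficiency is the difference between the Ribo-seq and RNA-seq changes in 1 model of both assays, and the difference in arsenite response is an interaction. Standard errors of log2 fold changes are the estimate divided by the square root of its F. Values in CPM use TMM-scaled library sizes. The fits held 26 RNA-seq, 28 Ribo-seq and 54 efficiency libraries, 6, 6 and 12 for siRNA, 4 for LTM, 6 for Sel-TCP-seq and 6 for the knock-in cells. Their residual degrees of freedom were 14, 14, 28, 3, 3, 6, 2, 3 and 4, and the biological coefficients of variation 5.3%, 8.73%, 6.22%, 2.97%, 7.54%, 4.22%, 4.6%, 7.8% and 7.33%. Replicates differed by more than counting noise in each of 43 pairs (chi-square per gene 1.86 to 22.4, median 3.67).

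The comparisons, the genes to name, the gene lists and most alternatives were fixed before the data were examined. Genes to name were the targeted genes first; then, per comparison, up to 10 with the highest and 10 with the lowest log2 fold change among those past the threshold, with a mean log2 CPM of at least 3, the same direction in each line or siRNA and a symbol that is no identifier or pseudogene; up to 4 members of each list that passed, by size of change; JUN and BTG1 for Sel-TCP-seq; and ATF4, ATF5, PPP1R15A, PPP1R15B, SLC35A4, IFRD1, HMOX1 and DNAJB1 for arsenite. The text names part of these, and EIF3G and COX6A1 were chosen after their values were seen.

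The 27 gene lists, written from general knowledge, were: uORF mRNAs translated under eIF2α phosphorylation, ATF4 target genes, unfolded protein response, heat shock, NRF2 targets, metallothioneins and zinc export, immediate early genes, p53 targets, interferon response, cytosolic ribosomal proteins, other TOP mRNAs, ribosome biogenesis, cytosolic aminoacyl-tRNA synthetases, initiator tRNA delivery factors, start codon stringency factors, cap-binding and scanning factors, eIF3 subunits, genes with non-AUG initiated proteins, mitochondrially encoded mRNAs, nuclear oxidative phosphorylation subunits, histones, G2/M, cholesterol synthesis, polyamine pathway, HEK lineage markers, fibroblast markers and blood cell markers. Of the histone list 11 of 50 and of the uORF list 1 of 13 names matched no gene. Fewer than 3 blood cell markers were measured in any comparison, so that list was not tested. The other 26 were tested with camera of limma with a preset correlation of 0.01, adjusted within each comparison (617 tests). Counts of members "adjusted over the list alone" adjust edgeR's p over the members.

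Protein-coding depth is given with the report. On simulated counts with 200 changed genes, the test recovered 43.4% of genes changed 1.5-fold and 82.8% of those changed 3-fold for arsenite in WT Ribo-seq. The shares were 79% and 93% for arsenite in WT RNA-seq, 27% and 76.8% for the difference in footprint response of eIF2A KO, 63.3% and 96.9% for efficiency in eIF2A KO and 41.2% and 83% for the eIF3D against the eIF3B pulldown. Similarity of genotypes was compared with 20 simulations of unchanged groups on the same control libraries.

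Other settings fixed beforehand were DESeq2 1.42.0 with its own size factors, RLE factors, no count filter, a replicate block, leaving out each library, only the libraries of the compared groups, each line or siRNA alone, voom with sample quality weights for comparisons of efficiency, and, for lists, an estimated correlation and fry. Added after the data were seen were the sum of transcripts per gene, each pair of WT RNA-seq columns alone, the efficiency fit without eIF2A KO RNA-seq, and both lines or siRNAs as 1 group. That last fit has no term for the line or siRNA. Differences between lines that cancel in an efficiency or an arsenite response thus enter its spread. Shares at transcript ends used genes with a short transcript that starts or ends within 200 nt of the representative transcript's end, lies at least 95% inside it and has at most 50% of its length, with at least 50 counts in each kind of library. Python 3.11.15 (numpy 2.4.6, pandas 2.3.3) named the genes and matplotlib 3.10.9 drew the figures.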

Results

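The data came from HEK293T, a human embryonic kidney cell line, and comprised 82 columns, 78 of them distinct libraries, of 4 kinds. RNA-seq measured mRNA levels, and ribosome profiling (Ribo-seq) measured the mRNA fragments covered by elongating ribosomes. GTI-seq used lactimidomycin (LTM), a drug that holds newly initiated ribosomes at start sites. Selective translation complex profiling (Sel-TCP-seq) measured mRNA fragments held by small ribosomal subunits, either all of them (40S input) or those recovered with the initiation factor subunits eIF3D or eIF3B. The series asks how start sites are found and which initiation factors act there, eIF2 and near-cognate codons among them. The counts are per transcript, so single start codons were not analysed here. Cells were wild type (WT), knockouts (KO) of eIF2A or eIF2D, double knockouts of both, cells transfected with siRNA against eIF2α, or cells carrying tagged eIF3D. Each knockout was represented by 2 lines and the siRNA treatment by 2 siRNAs, with 2 libraries per line, treatment and assay; untreated WT RNA-seq had 4. Arsenite, a stressor that triggers phosphorylation of eIF2α, was given at 40 µM for 60 min. Protein-coding genes held 11.52 to 46.8 M counts (M, mega) per RNA-seq library (median 25.98, n = 34 distinct libraries), 1.58 to 19.83 M per ribosome footprint library (median 6.55, n = 38) and 2.13 to 2.93 M per Sel-TCP-seq library (n = 6). Replicates are not stated to be separate cultures, so p-values measure spread between these samples, which may be technical. For knockouts and siRNAs, main tests and SEs rest on spread within lines or siRNAs, not between them. Normalisation removes any change common to all genes, so each change is relative to the other genes of the same library.

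Targeted genes were examined first, as a check of the labels. EIF2A (ENST00000487799.5, GRCh38 chromosome 3, 150546685 to 150584023, full transcript) encodes a factor able to bring initiator tRNA to ribosomes without eIF2. Its footprints were 158 ± 1.07 CPM (normalised counts; SD, n = 2) in WT, 27.1 ± 4.21 and 8.46 ± 0.874 in eIF2A KO lines 1 and 2, and 22.1 ± 2.15 and 18.8 ± 0.823 in the double KO lines. EIF2A mRNA was 111 ± 2.0 CPM in WT (n = 4), 33.3 ± 3.56 in eIF2A KO line 2 and 103 ± 1.44 in line 1, where it did not differ from WT (log2 fold change −0.11, adjusted p = 0.187). EIF2D (ENST00000271764.7, chromosome 1, 206591642 to 206612465) encodes a further factor that binds initiator tRNA. Its footprints fell from 61.9 ± 4.2 CPM in WT to 7.28 ± 2.33 and 6.24 ± 1.44 in the eIF2D KO lines and to 5.72 ± 1.79 and 6.36 ± 0.889 in the double KO lines. EIF2D mRNA fell from 97.2 ± 2.55 CPM (n = 4) to 52.1 ± 1.92 and 40.1 ± 1.72 in the eIF2D KO lines. EIF2S1 (ENST00000256383.9, chromosome 14, 67360328 to 67386516), which encodes eIF2α, fell in RNA-seq from 141 ± 3.14 CPM with control siRNA to 10.4 ± 1.2 with siRNA 1 and 11.8 ± 0.61 with siRNA 2. Its footprints were 243 ± 3.45 CPM with control siRNA, 99.6 ± 7.71 with siRNA 1 and 409 ± 67.8 with siRNA 2, so in the libraries labelled siRNA 2 the footprints of EIF2S1 went against the label while its mRNA went with it. EIF3D (ENST00000216190.13, chromosome 22, 36510855 to 36529166) changed from 291 ± 15.1 CPM in WT (n = 4) to 228 ± 2.88 in the eIF3D-V5 knock-in cells (n = 2), a log2 fold change of −0.35 ± 0.06 (SE). EIF4E, the cap-binding protein that the column headers name as also tagged in these cells, rose from 47.3 ± 3.98 to 257 ± 4.47 CPM (log2 2.44 ± 0.07).

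**Figure D1:**
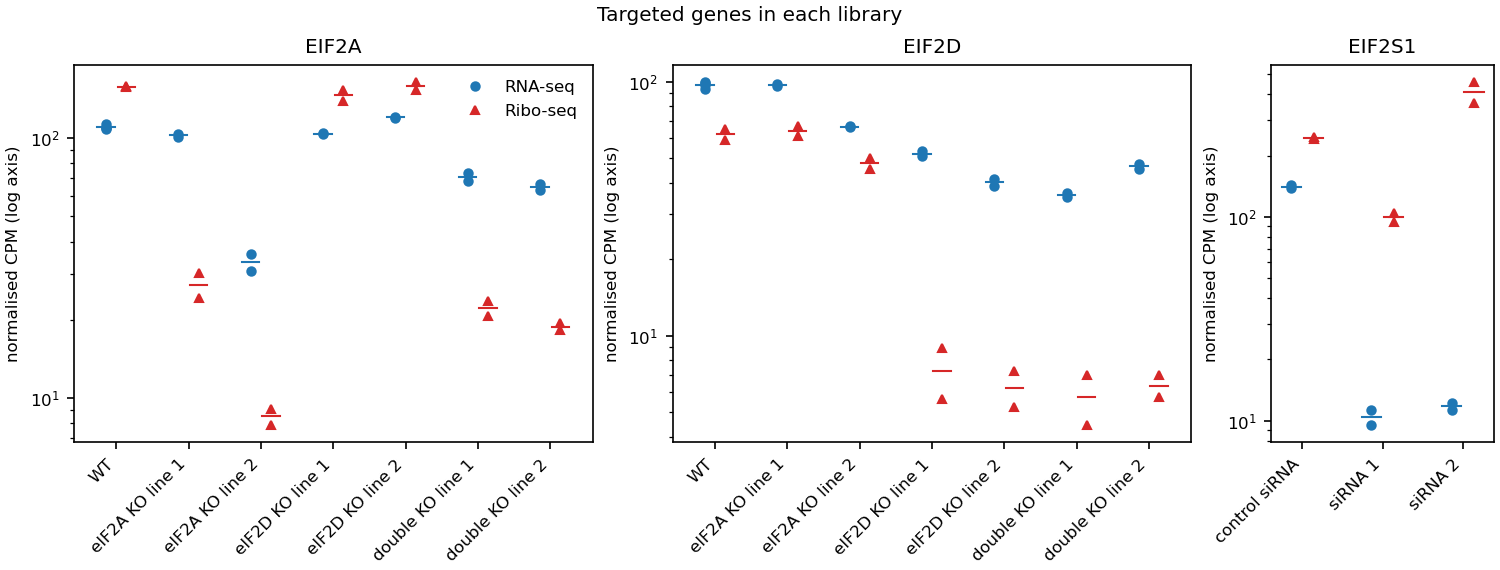
CPM (log axis) of EIF2A, EIF2D and EIF2S1 in each library of each group, for RNA-seq (circles) and Ribo-seq (triangles); short lines are means of 2 libraries, or 4 for WT RNA-seq. EIF2A footprints were 158 CPM in WT and 8.46 to 27.1 in the eIF2A KO lines, while EIF2S1 footprints were higher with siRNA 2 than with control siRNA.

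In WT cells, arsenite raised the footprints of mRNAs whose upstream open reading frames (uORFs) are known to allow translation when eIF2α is phosphorylated. Of 12 measured members, 11 rose (11 adjusted over the list alone, median log2 fold change 1.20, list test adjusted p = 4.32e-21, and 1.68e-06 with an estimated correlation). Lists are named below where they passed this test with a preset correlation, unless the text says otherwise. PPP1R15A, the phosphatase subunit that reverses eIF2α phosphorylation, rose by 3.69 ± 0.15 (log2 ± SE, 2 libraries against 2), IFRD1, a transcriptional co-regulator, by 2.02 ± 0.13, ATF4, the main transcription factor of the integrated stress response, by 1.89 ± 0.10, PPP1R15B by 1.28 ± 0.08 and SLC35A4 by 0.85 ± 0.10. Footprints of immediate early genes rose for 18 of 32 (19 adjusted over the list alone, adjusted p = 0.000465 with an estimated correlation). EGR1 was at 4.89 ± 0.51, FOS at 4.12 ± 0.23 and DUSP1 at 2.69 ± 0.10. Ribosome biogenesis genes rose for 15 of 21 (15 adjusted over the list alone, adjusted p = 0.0593 with an estimated correlation) and heat shock genes for 9 of 18 (11 higher and 2 lower adjusted over the list alone, adjusted p = 0.118 with an estimated correlation). Among the latter were the chaperone HSPA8 (0.90 ± 0.07) and its co-chaperone BAG3 (0.95 ± 0.09). HMOX1 (−0.15 ± 0.11) and DNAJB1 (0.34 ± 0.14, adjusted p = 0.0621) did not pass the test, although DNAJB1 did with DESeq2 (adjusted p = 0.0325), with RLE scaling (0.0345) and with WT libraries alone (0.0369).

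Other groups lost footprints relative to the rest with arsenite. Histone mRNAs fell for 24 of 35 and rose for 3 (24 and 3 adjusted over the list alone, adjusted p = 0.0593 with an estimated correlation). H3C12 was at −0.99 ± 0.07. Cytosolic ribosomal protein mRNAs fell for 37 of 80 and rose for 9 (38 and 9 adjusted over the list alone, median −0.291, adjusted p = 0.413 with an estimated correlation). RPS18 was at −0.83 ± 0.10 and RPL39, at 4.89 ± 0.22, moved the other way. Further mRNAs with a 5′ terminal oligopyrimidine (TOP) tract fell for 7 of 18 and rose for 3 (8 and 4 adjusted over the list alone, adjusted p = 0.303 with an estimated correlation). PABPC1, the poly(A)-binding protein, was at −2.89 ± 0.10, CCNI at −2.97 ± 0.12, EIF4EBP2, a repressor of cap-dependent initiation, at −2.47 ± 0.23, and EIF1, which enforces start codon choice, at −0.94 ± 0.08. Of the 5 start codon stringency factors, 3 fell and 1 rose (4 and 1 adjusted over the list alone, adjusted p = 0.216 with an estimated correlation). Mitochondrially encoded mRNAs rose for 12 of 13 (13 adjusted over the list alone, median 1.74, adjusted p = 0.0923 with an estimated correlation). ND5 was at 2.13 ± 0.20. Mitochondrial rRNA moved with them, holding 8.52% and 5.40% of the counts of named genes in the treated WT libraries and 0.663% and 1.30% in the untreated ones. In all, 4852 of 12975 genes changed (2193 higher, 2659 lower) in the quasi-likelihood test of edgeR at an adjusted p of 0.05.

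Translational efficiency, footprints relative to mRNA, changed for 4697 of 12855 genes with arsenite in WT (1965 higher, 2732 lower). The uORF mRNAs rose for 10 of 12 (11 adjusted over the list alone, median 1.165, adjusted p = 3.74e-09 with an estimated correlation). PPP1R15A rose by 2.88 ± 0.16, IFRD1 by 1.97 ± 0.15, ATF4 by 1.93 ± 0.12, PPP1R15B by 1.38 ± 0.10 and SLC35A4 by 1.04 ± 0.10 (log2 ± SE, 2 Ribo-seq and 2 RNA-seq libraries treated against 2 and 4 untreated). Mitochondrially encoded mRNAs rose for 13 of 13 (13 adjusted over the list alone, adjusted p = 0.154 with an estimated correlation). Efficiency fell for 10 of 18 other TOP mRNAs and rose for 2 (11 and 2 adjusted over the list alone, adjusted p = 0.213 with an estimated correlation). Among those lower were PABPC1 (−2.94 ± 0.12) and NPM1 (−0.96 ± 0.11). Efficiency also fell for 10 of 20 cholesterol synthesis genes (12 adjusted over the list alone, adjusted p = 0.213 with an estimated correlation). Ribosomal protein mRNAs fell for 33 of 80 and rose for 7 (36 and 9 adjusted over the list alone, adjusted p = 0.863 with an estimated correlation), RPL39 rising by 4.75 ± 0.23. Against the first-listed and second-listed pair of WT RNA-seq columns alone, which differ in mitochondrial mRNA (5.56% and 5.60% against 3.60% and 3.61% of counts), 4571 and 4474 genes changed.

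**Figure D2:**
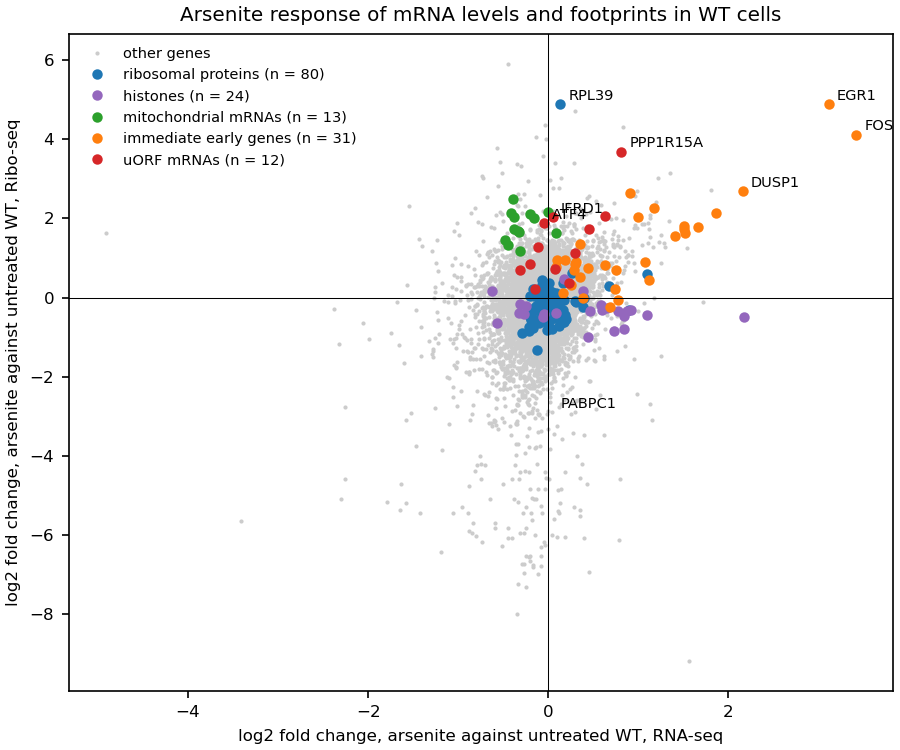
Log2 fold change of footprints (y axis) against that of mRNA (x axis) with arsenite in WT cells, 1 point per gene, with members of 5 gene lists in colour. Immediate early genes lie to the right and above, while ATF4, a uORF mRNA, rose in footprints (1.89) but not in mRNA (−0.05).

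At the mRNA level, arsenite in WT raised immediate early genes, the fast transcriptional response to stimuli, for 25 of 31 (28 adjusted over the list alone, median 0.755, adjusted p = 3.87e-05 with an estimated correlation). FOS rose by 3.42 ± 0.12, EGR1 by 3.12 ± 0.38, DUSP1 by 2.16 ± 0.08, CCN1 by 1.86 ± 0.10, JUN by 1.66 ± 0.09 and the stress-induced ATF3 by 1.41 ± 0.12 (log2 ± SE, 2 libraries against 4). Heat shock genes rose for 13 of 20 and fell for 1 (14 and 2 adjusted over the list alone, adjusted p = 0.0155 with an estimated correlation). HSPA8 was at 0.46 ± 0.04. Ribosome biogenesis genes rose for 15 of 21 (18 adjusted over the list alone, adjusted p = 0.0292 with an estimated correlation). NCL, nucleolin, was at 0.42 ± 0.04. Cytosolic aminoacyl-tRNA synthetases rose for 14 of 20 (14 adjusted over the list alone, adjusted p = 0.0292 with an estimated correlation) and G2/M genes for 11 of 20 (11 higher and 1 lower adjusted over the list alone, adjusted p = 0.0307 with an estimated correlation). NRF2 target genes rose for 9 of 22 and fell for 2 (9 and 2 adjusted over the list alone, adjusted p = 0.0386 with an estimated correlation). HMOX1, a classic target of NRF2, was at 0.11 ± 0.05 (adjusted p = 0.124) and passed the test with transcripts summed per gene (adjusted p = 0.0425). ATF4 target genes rose for 21 of 37 and fell for 1 (22 and 1 adjusted over the list alone, adjusted p = 0.0673 with an estimated correlation), including CHAC1 (1.30 ± 0.16) and SLC3A2 (0.96 ± 0.08). Metallothionein and zinc export genes rose for 2 of 4 (2 adjusted over the list alone, adjusted p = 0.0673 with an estimated correlation). The zinc exporter SLC30A1 changed by 1.23 ± 0.17 and the metal-binding MT1X by 0.93 ± 0.11. PPP1R15A mRNA rose by 0.81 ± 0.08 and ATF4 mRNA was at −0.05 ± 0.05. GAS1 (−0.95 ± 0.08) and TGFBR2 (−0.97 ± 0.10), a receptor of TGF-β, fell. In all, 3881 of 14519 genes changed (1878 higher, 2003 lower), 4314 and 3400 against each pair of WT columns, and 1554 (910 higher, 644 lower) when only WT libraries entered the fit. The 2 treated WT libraries stood apart, with a chi-square per gene of 18.75 between them against 5.272 to 6.287 within treated KO lines.

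With eIF2A KO, footprints of EIF2A fell by 3.36 on the log2 scale (SE 0.10, 4 KO libraries of 2 lines against 2 WT). Footprints of the neuronal CRMP1 were at −2.03 ± 0.22 and those of SERPINF1, a secreted serpin, at −2.19 ± 0.24. Nuclear genes for subunits of oxidative phosphorylation lost footprints for 11 of 34 and gained them for 1 (18 and 1 adjusted over the list alone, adjusted p = 0.0058 with an estimated correlation). Among those lower was UQCRC1 of complex III (−0.42 ± 0.05). ATF4 target genes lost footprints for 7 of 36 and gained them for 1 (11 and 2 adjusted over the list alone, adjusted p = 0.0398 with an estimated correlation). In RNA-seq, ATF4 target genes were lower for 18 of 37 and higher for 1 (20 and 1 adjusted over the list alone, adjusted p = 0.968 with an estimated correlation), including PCK2, a mitochondrial enzyme of gluconeogenesis (−0.72 ± 0.09). Oxidative phosphorylation genes were lower for 19 of 34 and higher for 1 (21 and 2 adjusted over the list alone, adjusted p = 0.982 with an estimated correlation). UQCRC1 was at −0.39 ± 0.04. Mitochondrially encoded mRNAs were lower for 11 of 13 (11 adjusted over the list alone, adjusted p = 0.982 with an estimated correlation). They held 3.221% to 3.493% of counts in the KO libraries, 5.555% and 5.601% in the first-listed WT pair and 3.596% and 3.612% in the second, so most of this difference lies with 1 WT pair. CRMP1 (−1.58 ± 0.07), PRKCB, a protein kinase C (−2.31 ± 0.12), and ZCCHC12 (−2.39 ± 0.06) fell, and NMNAT2, an enzyme of NAD synthesis (1.06 ± 0.09), and QPCT (1.05 ± 0.11) rose. Translational efficiency changed for 18 of 12855 genes (7 higher, 11 lower), EIF2A itself at −2.44 ± 0.11 and EXOC2 of the exocyst at −0.56 ± 0.07. Of 80 ribosomal protein mRNAs, 1 rose in efficiency (17 adjusted over the list alone, adjusted p = 0.348 with an estimated correlation).

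The number of genes behind these values depended on the lines, and the RNA-seq columns labelled eIF2A KO hold the same values for untreated and arsenite-treated cells in all 226882 transcript rows, so which treatment they measured is not settled by the labels. In RNA-seq, 4556 of 14519 genes changed in eIF2A KO (2009 higher, 2547 lower), 3236 in line 1 and 5909 in line 2 alone, 1092 the same way in each line alone, and 682 with both lines as 1 group. In Ribo-seq 910 changed (269 higher, 641 lower), 623 in line 1 and 1933 in line 2, 142 the same way in each, and 18 as 1 group; without WT library 1, WT library 2 or library 1 of line 2 the count was 318, 356 and 602. With both lines as 1 group, the calls of EIF2A (adjusted p = 0.0995), CRMP1 (0.0847), PRKCB (0.325) and ZCCHC12 (0.108) in RNA-seq, of CRMP1 in Ribo-seq (0.802) and of EXOC2 in efficiency (1) ended. Against each pair of WT RNA-seq columns, 4861 and 3475 genes changed in RNA-seq and 332 and 11 in efficiency.

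In the eIF2D KO lines NEFM, a neurofilament subunit expressed by HEK293T cells, was at −5.49 ± 0.06 in RNA-seq (log2 ± SE, 4 KO libraries of 2 lines against 4 WT) and −5.69 ± 0.14 in Ribo-seq (4 against 2). The double KO lines, which also lack eIF2D, held it at 188 and 223 CPM against 163 in WT RNA-seq. EIF2D itself was at −1.09 ± 0.04 in RNA-seq, −3.18 ± 0.16 in Ribo-seq and −2.08 ± 0.14 in efficiency. HEK lineage markers, which include NEFM, were lower for 5 of 9 and higher for 2 in RNA-seq (6 and 2 adjusted over the list alone, adjusted p = 0.00283 with an estimated correlation), KRT8, a keratin, among them (−0.55 ± 0.08), and lower for 2 of 9 in Ribo-seq (2 adjusted over the list alone, adjusted p = 0.00128 with an estimated correlation). Cholesterol synthesis genes lost footprints for 9 of 20 and gained them for 1 (9 and 1 adjusted over the list alone, adjusted p = 0.00128 with an estimated correlation). LSS, lanosterol synthase, was at −0.76 ± 0.08, INSIG1 at −0.73 ± 0.08 and SQLE at −0.52 ± 0.05. Immediate early genes gained footprints for 8 of 32 (15 higher and 1 lower adjusted over the list alone, adjusted p = 0.00754 with an estimated correlation). Of the phosphatases among them, DUSP5 was at 1.99 ± 0.25 and DUSP1 at 0.93 ± 0.09. ATF4 target genes lost footprints for 11 of 36 and gained them for 2 (14 and 2 adjusted over the list alone, adjusted p = 0.00299 with an estimated correlation). PCK2 was at −0.94 ± 0.11 and the mTORC1 inhibitor DDIT4 at −1.17 ± 0.10. In RNA-seq, ATF4 target genes were lower for 24 of 37 and higher for 5 (24 and 5 adjusted over the list alone, adjusted p = 0.434 with an estimated correlation). Unfolded protein response genes were lower for 11 of 20 and higher for 2 (11 and 2 adjusted over the list alone, adjusted p = 0.725 with an estimated correlation). XBP1 was at −0.68 ± 0.05. G2/M genes were higher for 11 of 20 and lower for 2 (11 and 2 adjusted over the list alone, adjusted p = 0.287 with an estimated correlation). CCNB1 was at 0.44 ± 0.03 and MKI67 at 0.38 ± 0.05. ENC1 (1.28 ± 0.07) and the growth hormone receptor GHR (1.19 ± 0.11) rose, and the fatty acid desaturase FADS2 (−1.68 ± 0.07) fell.

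Translational efficiency in eIF2D KO rose for 17 of 80 ribosomal protein mRNAs (43 adjusted over the list alone, median 0.225, adjusted p = 0.138 with an estimated correlation). RPL10A changed by 0.55 ± 0.09 and RPS19 by 0.47 ± 0.09 (log2 ± SE). Efficiency also rose for 4 of 18 other TOP mRNAs (6 higher and 1 lower adjusted over the list alone, adjusted p = 0.361 with an estimated correlation). TPT1 changed by 0.36 ± 0.07. NCL (−0.47 ± 0.07), CADPS2, a factor of vesicle release (−1.01 ± 0.13), and APC2 (−2.66 ± 0.45) fell. In all, 6019 of 14519 genes changed in RNA-seq (2735 higher, 3284 lower), 2508 the same way in both lines and 1981 with the lines as 1 group; 1484 in Ribo-seq (617 higher, 867 lower), 528 and 163; and 180 in efficiency (59 higher, 121 lower), 38 and 10. Against each pair of WT RNA-seq columns, 5941 and 5060 genes changed in RNA-seq and 743 and 91 in efficiency, and without WT footprint library 1 or 2 the Ribo-seq count was 658 and 689. With the lines as 1 group the calls of GHR in RNA-seq (adjusted p = 0.0619), INSIG1 in Ribo-seq (0.404) and the efficiency calls of the 6 genes named in this paragraph ended (0.146 to 1), TPT1 also with transcripts summed per gene (0.123) and RPL10A with the compared libraries alone (0.0723).

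In double knockout cells RUNX1T1, a transcriptional corepressor, fell by 2.07 on the log2 scale in RNA-seq (SE 0.09) and 1.96 in Ribo-seq (SE 0.22). SNAI2, a repressor of epithelial genes (−1.54 ± 0.10), CA2, carbonic anhydrase (−1.60 ± 0.04), and the cell cycle inhibitor CDKN1A (−1.49 ± 0.24) were lower in RNA-seq. ITPR3, a calcium channel of the endoplasmic reticulum (0.71 ± 0.06), and the Wnt receptor FZD6 (0.74 ± 0.10) were higher. In Ribo-seq APOE, a lipid carrier (−2.13 ± 0.18), and SERPINF1 (−2.46 ± 0.24) fell and ANXA1 rose (1.83 ± 0.29). No list passed its test in RNA-seq. In Ribo-seq the initiator tRNA delivery factors fell for 3 of 19 (adjusted p = 0.0174 with an estimated correlation). The list holds the targeted EIF2A (−2.96) and EIF2D (−3.37), so its test does not speak for the others. Ribosomal protein mRNAs rose for 8 of 80 (17 higher and 1 lower adjusted over the list alone, adjusted p = 0.442 with an estimated correlation). In efficiency, EIF2A was at −2.26, EIF2D at −2.13 and CADPS2 at −0.92 ± 0.13, and 5 of 80 ribosomal protein mRNAs rose (24 adjusted over the list alone, adjusted p = 0.265 with an estimated correlation). In all, 4951 genes changed in RNA-seq (2154 higher, 2797 lower; 6540 in line 1, 3181 in line 2, 1081 the same way in both, 473 as 1 group), 741 in Ribo-seq (209 higher, 532 lower; 1838, 582, 117 and 6) and 84 in efficiency (16 higher, 68 lower; 69, 34, 16 and 7). With the lines as 1 group the calls of EIF2A (adjusted p = 0.105), CA2 (0.194) and SNAI2 (0.0906) in RNA-seq, ANXA1 (0.458) and APOE (0.741) in Ribo-seq and CADPS2 in efficiency (0.345) ended. Against each pair of WT RNA-seq columns 5115 and 3657 genes changed in RNA-seq and 473 and 44 in efficiency, and the Ribo-seq count was 232 and 249 without WT library 1 and 2, 459 without library 2 of line 1, and 457 and 468 without libraries 1 and 2 of line 2.

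**Figure D3:**
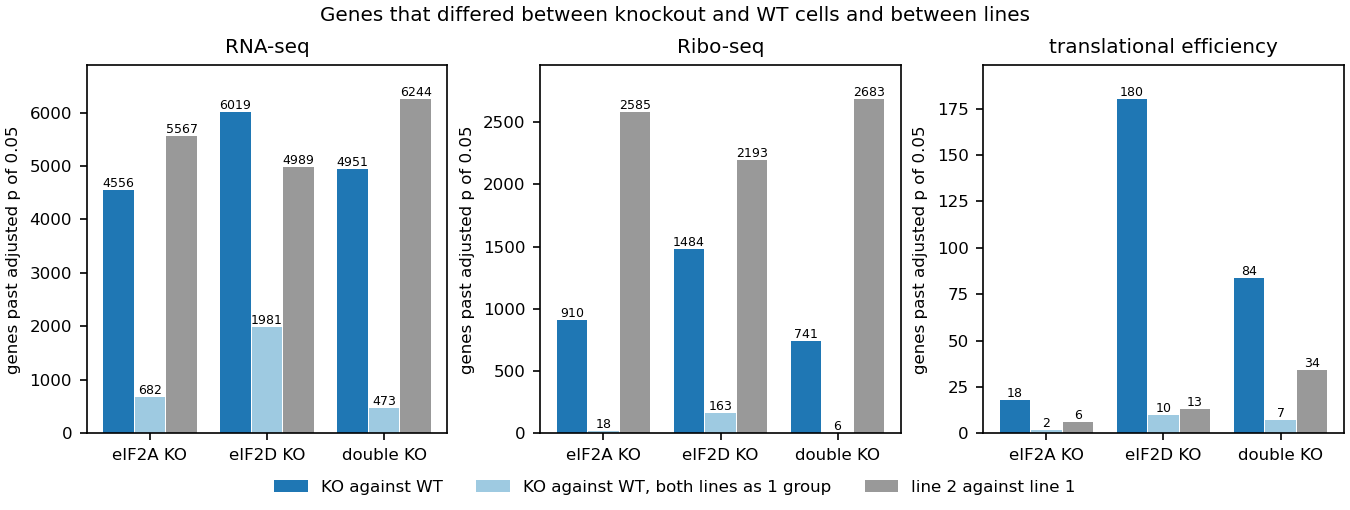
Number of genes past an adjusted p of 0.05 for each knockout against WT, the same with both lines treated as 1 group, and line 2 against line 1, in RNA-seq, Ribo-seq and translational efficiency. In RNA-seq the lines of 1 genotype differed in 4989 to 6244 genes, and in efficiency knockouts differed from WT in 18 to 180.

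Between eIF2A KO and eIF2D KO, the correlation of fold changes across genes was 0.387 in RNA-seq and 0.376 in Ribo-seq. Genes are not independent replicates. Between eIF2A KO and double KO it was 0.437 and 0.517, and between eIF2D KO and double KO 0.455 and 0.502. These comparisons share the WT libraries, and simulated unchanged groups gave 0.534 to 0.537 in RNA-seq and 0.651 to 0.661 in Ribo-seq. Covariances were 0.0726, 0.0754 and 0.0957 in RNA-seq against 0.0142, 0.0143 and 0.0140 simulated, which may be too low as the WT pairs differ. In Ribo-seq they were 0.0785, 0.0994 and 0.105 against 0.0623, 0.0620 and 0.0611. In RNA-seq 742 genes were higher in both eIF2A KO and eIF2D KO, 987 lower in both and 673 changed in opposite directions, counts that the shared WT libraries also affect. With a separate pair of WT columns for each genotype, in either assignment, 542 and 434 were higher in both (359.7 and 291.5 for independent lists), 727 and 643 lower in both (509.6 and 440) and 845 and 704 opposite, and the RNA-seq correlations of the 3 pairs of genotypes were 0.132 to 0.239. Against the first-listed pair alone they were 0.620, 0.667 and 0.648 in the same order, and against the second-listed pair alone 0.412, 0.445 and 0.470.

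Arsenite was also given to the knockout lines, which asks whether the stress response needs eIF2A or eIF2D. In the knockouts, footprints of uORF mRNAs rose for 12 of 12 in each genotype, by a median log2 of 0.856 in eIF2A KO, 1.05 in eIF2D KO and 0.894 in double KO, beside 11 of 12 and 1.20 in WT. The test of the difference itself put the list lower than in WT in eIF2A KO (1 of 12 genes lower, 7 adjusted over the list alone, adjusted p = 0.00151 with an estimated correlation) and double KO (2 of 12, 5 adjusted over the list alone, adjusted p = 0.0146 with an estimated correlation), and in eIF2D KO (2 of 12 adjusted over the list alone, adjusted p = 0.0524 with an estimated correlation). The PPP1R15A response differed from that in WT by −1.07 ± 0.18 in eIF2A KO (adjusted p = 0.00211, and 0.0538 without WT library 2) and −0.78 ± 0.17 in double KO (0.0161, and 0.0602 and 0.16 without WT library 1 and 2), while in eIF2D KO the difference was −0.48 ± 0.17 and did not pass. The ATF4 difference was −0.51 ± 0.12 in double KO (0.0405; the call ended without each of 10 of the 12 libraries, at 0.0502 to 0.204, and with the compared libraries alone, at 0.139), −0.46 ± 0.12 in eIF2A KO (0.13, but 0.0216 with DESeq2 and 3.65e-05 without a filter) and −0.33 in eIF2D KO (0.279, but 0.0434 with the compared libraries alone and 0.0152 without a filter). HMOX1, which encodes haem oxygenase, responded more in double KO (0.70 ± 0.14). In eIF2D KO, ribosomal protein mRNAs responded lower than in WT for 25 of 80 (51 adjusted over the list alone, median −0.348, adjusted p = 0.00793 with an estimated correlation). RPL39 differed by −1.29 ± 0.27 (adjusted p = 0.00819, and 0.22 without WT library 2 and 0.053 without library 2 of line 1). Other TOP mRNAs did so for 8 of 18 (14 adjusted over the list alone, adjusted p = 0.00793 with an estimated correlation) and histones for 6 of 35 (20 adjusted over the list alone, adjusted p = 0.00793 with an estimated correlation). In efficiency, ribosomal protein mRNAs responded lower in eIF2D KO for 10 of 80 (43 adjusted over the list alone, adjusted p = 0.0309 with an estimated correlation). RPL10A differed by −0.86 ± 0.14. Other TOP mRNAs responded lower for 3 of 18 (10 adjusted over the list alone, adjusted p = 0.0299 with an estimated correlation). Cap-binding and scanning factors responded lower there for 1 of 14 (1 higher and 2 lower adjusted over the list alone, adjusted p = 0.216 with an estimated correlation). The efficiency response of ATF4 in double KO differed by −0.63 ± 0.14 (adjusted p = 0.0244), a call that ended without footprint library 2 of untreated WT (0.0921), footprint library 1 (0.073) or RNA-seq library 1 (0.0868) of treated WT, with the second-listed WT pair (0.0706), with voom (0.123) and with the compared libraries alone (0.0741).

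The footprint response to arsenite differed from that of WT for 29 genes in eIF2A KO (9 higher, 20 lower), 117 in eIF2D KO (36 higher, 81 lower) and 179 in double KO (73 higher, 106 lower). The efficiency response differed for 51 genes in eIF2D KO (24 higher, 27 lower) and 73 in double KO (42 higher, 31 lower), and for 234 and 31 (eIF2D KO) and 336 and 41 (double KO) against each pair of WT RNA-seq columns. With both lines as 1 group, edgeR called 0, 1 and 0 genes in Ribo-seq and 0 and 0 in efficiency at an adjusted p of 0.05, and 629, 516, 695, 508 and 589 at an unadjusted p under 0.05; the calls of the genes named above ended. With the lines apart, DESeq2 called 116, 197 and 431 in Ribo-seq and 150 and 232 in efficiency. Transcripts summed per gene also ended the Ribo-seq calls of PPP1R15A, ATF4, HMOX1, EIF2D and RPL39 (adjusted p = 0.0507 to 0.079). Leaving out single libraries moved these counts between 4 and 320, 33 and 154, 25 and 209, 22 and 102, and 23 and 287; each such library is named under the dependence on processing. The efficiency response of eIF2A KO could not be computed, because the RNA-seq columns of treated and untreated eIF2A KO cells are identical.

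**Figure D4:**
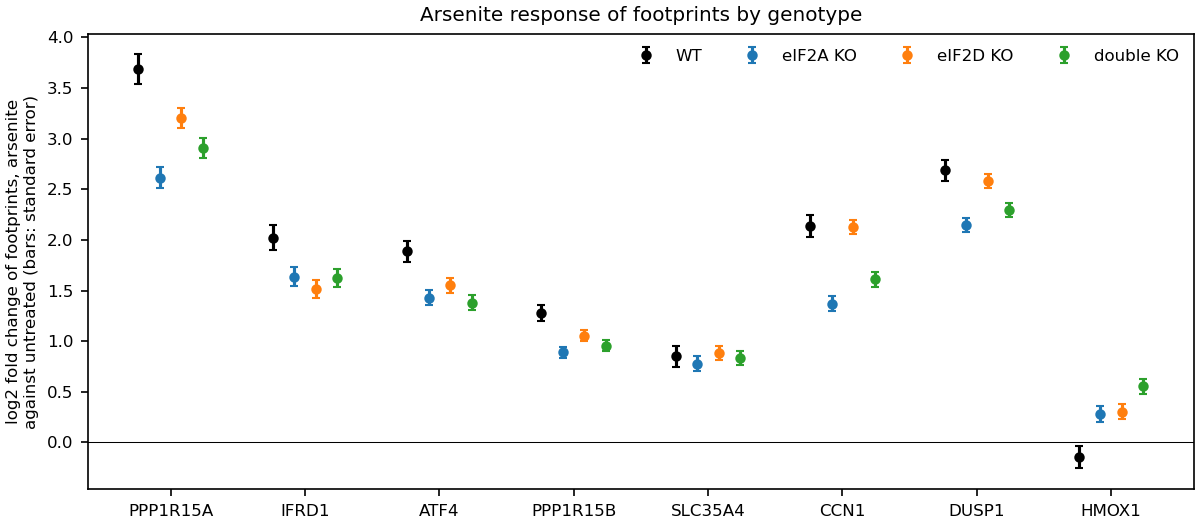
Log2 fold change of footprints with arsenite for 8 genes in WT, eIF2A KO, eIF2D KO and double KO cells; points are estimates from 2 libraries per line and treatment, bars are standard errors. PPP1R15A rose by 3.69 in WT and by less in the eIF2A KO and double KO, whereas SLC35A4 rose by 0.85 in WT and by 0.78, 0.88 and 0.83 in the knockouts.

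Depletion of eIF2α by siRNA raised target genes of ATF4 together. In RNA-seq 38 of 38 rose (38 adjusted over the list alone, median log2 1.94, adjusted p = 0.0522 with an estimated correlation) and in Ribo-seq 36 of 37 (36 adjusted over the list alone, adjusted p = 0.0408 with an estimated correlation). NUPR1, a stress-induced chromatin protein, rose by 5.93 ± 0.27, TRIB3, a pseudokinase induced by ATF4, by 3.27 ± 0.05, SESN2, which senses leucine, by 3.30 ± 0.04 and PCK2 by 3.31 ± 0.06 in RNA-seq (log2 ± SE, 4 libraries of 2 siRNAs against 2). In Ribo-seq TRIB3 rose by 3.89 ± 0.12, CHAC1, which degrades glutathione, by 3.64 ± 0.16 and SESN2 by 3.44 ± 0.07. Aminoacyl-tRNA synthetases rose for 14 of 20 and fell for 3 in RNA-seq (14 and 3 adjusted over the list alone, adjusted p = 0.116 with an estimated correlation) and rose for 12 of 20 and fell for 1 in Ribo-seq (12 and 1 adjusted over the list alone, adjusted p = 0.0408 with an estimated correlation). GARS1 changed by 1.85 ± 0.03 and 1.88 ± 0.06. The uORF mRNAs rose for 10 of 12 in footprints (10 adjusted over the list alone, adjusted p = 0.0525 with an estimated correlation) and for 10 of 12 in efficiency (10 adjusted over the list alone, median 0.74, adjusted p = 0.000825 with an estimated correlation): ATF4 by 1.62 ± 0.07 and 1.502 ± 0.07, PPP1R15A by 2.02 ± 0.24 and 1.27 ± 0.22, and IFRD1 in efficiency by 1.42 ± 0.08. Heat shock genes fell for 14 of 18 and rose for 2 in RNA-seq (14 and 2 adjusted over the list alone, adjusted p = 0.135 with an estimated correlation). HSPA1B was at −1.96 ± 0.03. Cholesterol synthesis genes fell for 13 of 20 and rose for 3 (13 and 3 adjusted over the list alone, adjusted p = 0.185 with an estimated correlation). CCND1, cyclin D1, was at −1.92 ± 0.08. In Ribo-seq HSPA1B was at −1.78 ± 0.07 and the linker histone gene H1-3 at −2.01 ± 0.07, and histones fell for 18 of 27 and rose for 2 (18 and 3 adjusted over the list alone, adjusted p = 0.448 with an estimated correlation). In efficiency, EIF1 was at −0.38 ± 0.06, H2BC5 at −1.60 ± 0.14 and RPL39 at 3.47 ± 0.36.

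With eIF2α siRNA 8359 of 13312 genes changed in RNA-seq (4122 higher, 4237 lower), 4387 of 10857 in Ribo-seq (2110 higher, 2277 lower) and 1624 of 10833 in efficiency (742 higher, 882 lower). With siRNA 1 alone the counts were 8260, 4126 and 1153, with siRNA 2 alone 7642, 3289 and 1148, and with both as 1 group 4528, 2306 and 121, where EIF1 (adjusted p = 0.21), H2BC5 (0.232) and EIF2S1 (0.0806) lost their efficiency calls. The fold changes of the siRNAs correlated at 0.782 in RNA-seq and 0.697 in Ribo-seq across genes (0.521 and 0.352 in simulated unchanged groups sharing the control libraries; covariances 0.295 and 0.304 against 0.0159 and 0.0263). DESeq2 called 2777 genes in Ribo-seq and transcripts summed per gene gave 2832 in Ribo-seq and 560 in efficiency; without control footprint library 1 the Ribo-seq count was 2745, and without control RNA-seq library 2 the efficiency count was 1011.

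LTM was compared with cycloheximide (CHX), an elongation inhibitor. LTM cells have no RNA-seq, so a change in mRNA cannot be set apart. Genes with known proteins begun at a non-AUG codon gained footprints for 13 of 16 (13 adjusted over the list alone, median log2 0.696, adjusted p = 0.462 with an estimated correlation). The oncogene MYC changed by 1.40 ± 0.05, the helicase DDX17 by 1.36 ± 0.04 and BAG1 by 1.17 ± 0.13 (log2 ± SE, 2 libraries against 2). Immediate early genes gained for 13 of 26 (13 adjusted over the list alone, adjusted p = 0.462 with an estimated correlation). EGR1 changed by 2.80 ± 0.34 and FOS by 2.37 ± 0.40. Of 5 start codon stringency factors 4 gained (4 adjusted over the list alone, adjusted p = 0.469 with an estimated correlation). EIF1 changed by 1.07 ± 0.05, its paralogue EIF1B by 1.00 ± 0.08 and EIF5 by 0.34 ± 0.06. Mitochondrially encoded mRNAs gained for 13 of 13 (13 adjusted over the list alone, adjusted p = 0.469 with an estimated correlation). ND6 changed by 1.45 ± 0.07, while mitochondrial rRNA held 4.86% and 5.14% of counts with LTM and 2.23% and 1.97% with CHX. Nuclear oxidative phosphorylation genes lost footprints for 22 of 34 and gained for 4 (23 and 4 adjusted over the list alone, adjusted p = 0.462 with an estimated correlation). NDUFS3 was at −1.82 ± 0.09. Histones lost footprints for 19 of 29 and gained for 5 (19 and 5 adjusted over the list alone, adjusted p = 0.469 with an estimated correlation). H3C13 was at −3.50 ± 0.14. Single genes at the ends of the range included RPL22 (3.24 ± 0.12), LIN7C (−3.61 ± 0.17) and the helicase cofactor EIF4H (−2.82 ± 0.13). In all, 6818 of 11522 genes changed (3328 higher, 3490 lower).

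Sel-TCP-seq of eIF3D-V5 against its 40S input asks which mRNAs lie under small subunits that carry this cap-binding subunit of eIF3. Ribosomal protein mRNAs were enriched for 65 of 80 and depleted for 9 (66 and 9 adjusted over the list alone, median log2 0.802, adjusted p = 0.403 with an estimated correlation). RPL39 was at 2.11 ± 0.11 and RPL41 at 1.94 ± 0.08 (log2 ± SE, 2 libraries against 2). NPM1, nucleophosmin, was at 2.28 ± 0.08. Heat shock genes were enriched for 12 of 18 and depleted for 3 (12 and 3 adjusted over the list alone, adjusted p = 0.486 with an estimated correlation). HSPA1B was at 1.68 ± 0.11 and HSP90AB1 at 1.64 ± 0.08, and EIF1 was at 0.94 ± 0.08. Mitochondrially encoded mRNAs were depleted for 13 of 13 (13 adjusted over the list alone, median −6.19, adjusted p = 0.403 with an estimated correlation). COX2 was at −6.28 ± 0.46, and mitochondrial rRNA held 1.37% and 1.34% of counts in the pulldown and 65.4% and 64.0% in the input. ATF4 target genes were depleted for 11 of 34 (9 adjusted over the list alone, adjusted p = 0.403 with an estimated correlation). ATP5F1B of the ATP synthase (−1.40 ± 0.09) and the amino acid transporter SLC38A2 (−0.82 ± 0.11) were lower. JUN (0.09 ± 0.10) and BTG1 (0.23 ± 0.15), mRNAs known to bind eIF3, did not pass the test. In all, 5230 of 11265 genes differed (2656 higher, 2574 lower).

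The eIF3D pulldown was made from the knock-in cells and the eIF3B pulldown, which carries the core of eIF3, from WT cells, so differences between the pulldowns include those between the cells (5279 of 13606 genes in RNA-seq). Against the eIF3B pulldown the eIF3D pulldown held more ribosomal protein mRNAs, 57 of 80 being higher (62 adjusted over the list alone, median log2 0.374, adjusted p = 0.152 with an estimated correlation). RPL39 was at 1.15 ± 0.10 and RPL12 at 0.87 ± 0.09. Histones were higher for 20 of 27 (22 higher and 1 lower adjusted over the list alone, adjusted p = 0.227 with an estimated correlation). H4C3 was at 0.77 ± 0.14. Nuclear oxidative phosphorylation genes were higher for 19 of 34 (23 adjusted over the list alone, adjusted p = 0.152 with an estimated correlation). COX6A1 was at 0.87 ± 0.08. Subunits of eIF3 were higher for 6 of 12 (7 adjusted over the list alone, adjusted p = 0.152 with an estimated correlation). EIF3G was at 0.59 ± 0.10. NPM1 (1.16 ± 0.07), HSP90AB1 (1.22 ± 0.08) and 3 of 8 polyamine pathway genes (3 adjusted over the list alone, adjusted p = 0.152 with an estimated correlation), including AMD1 (0.93 ± 0.13) and SRM (0.70 ± 0.15), were higher. Cholesterol synthesis genes were lower for 6 of 20 (8 lower and 1 higher adjusted over the list alone, adjusted p = 0.152 with an estimated correlation). INSIG1 was at −1.18 ± 0.10 and SQLE at −0.95 ± 0.09. ATF4 target genes were lower for 9 of 34 and higher for 1 (10 and 1 adjusted over the list alone, adjusted p = 0.152 with an estimated correlation). SLC38A2 was at −1.09 ± 0.11. JUN was lower (−0.72 ± 0.10) and BTG1 did not pass (−0.12 ± 0.14). In all, 1453 genes differed (771 higher, 682 lower), 715 (463 higher, 252 lower) with DESeq2, 515 with transcripts summed per gene, where SRM did not pass (adjusted p = 0.0547), and 811 and 948 without library 2 of the eIF3D or of the eIF3B pulldown.

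The position of the fragments along mRNAs also differed. For 2544 genes with a short annotated transcript at the 5′ end of the representative one (median 23.9% of its length), that transcript held a median of 88.1% ± 0.86 (SD, n = 2) of the counts in the eIF3D pulldown, 87.9% ± 1.39 in the eIF3B pulldown, 59.7% ± 0.09 in the 40S input, 56.9% ± 0.88 with LTM, 48.5% ± 0.07 with CHX and 37.1% ± 2.5 in WT RNA-seq (n = 4). For 438 genes with a short 3′ transcript (35.4% of length), the shares were 6.26% ± 0.2, 7.62% ± 0.25, 28.9% ± 0.18, 35.7% ± 0.23, 41.4% ± 0.34 and 50.6% ± 1.02. No p-value was computed for these shares.

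**Figure D5:**
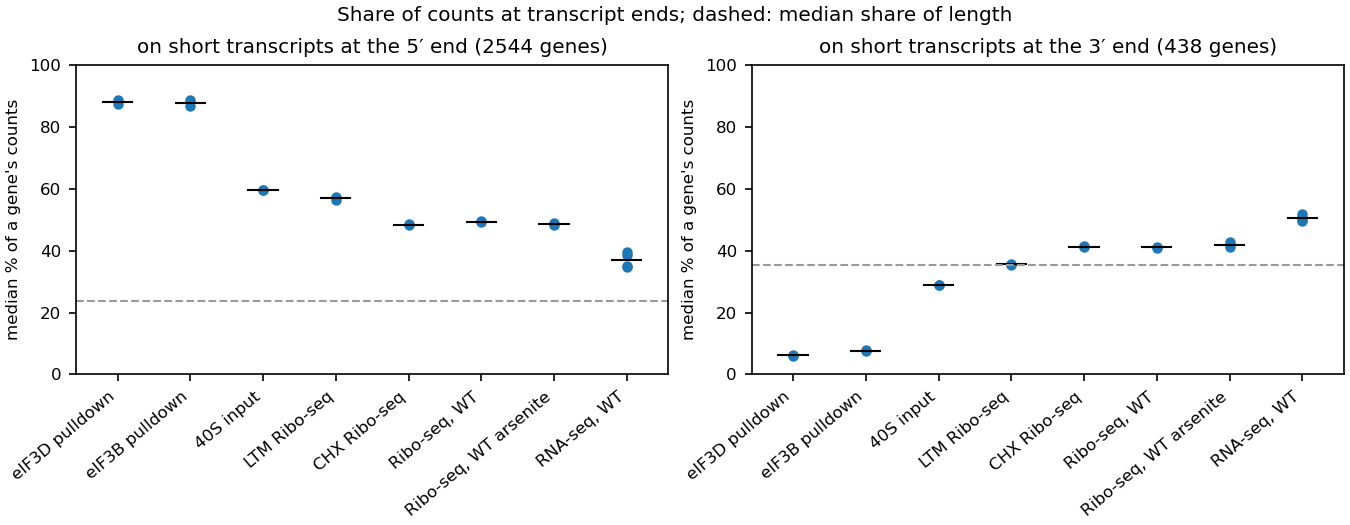
Median percent of a gene's counts that fell on a short transcript at the 5′ end (left, 2544 genes) or the 3′ end (right, 438 genes) of the representative transcript; points are libraries, short lines are group means and the dashed line is the median share of length. Both pulldowns lie near 88% at the 5′ end and at 6.26% to 7.62% at the 3′ end.

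Cells carrying tagged eIF3D were compared with WT in RNA-seq to show how far the modified line differs. Unfolded protein response genes were higher for 18 of 20 (18 adjusted over the list alone, median log2 0.406, adjusted p = 0.23 with an estimated correlation). HERPUD1 was at 1.30 ± 0.07, DNAJB9 at 1.27 ± 0.10 and XBP1 at 0.94 ± 0.09 (log2 ± SE, 2 libraries against 4). ATF4 target genes were higher for 28 of 37 (28 adjusted over the list alone, adjusted p = 0.315 with an estimated correlation). TRIB3 was at 1.38 ± 0.08. Immediate early genes were higher for 21 of 31 and lower for 2 (21 and 2 adjusted over the list alone, adjusted p = 0.315 with an estimated correlation). FOS was at 2.73 ± 0.16, FOSB at 2.60 ± 0.14 and ATF3 at 1.88 ± 0.10. Among genes with non-AUG initiated proteins 8 of 16 were lower and 2 higher (8 and 2 adjusted over the list alone, adjusted p = 0.23 with an estimated correlation). MYC was at −0.92 ± 0.07, EIF4G2 at −0.70 ± 0.05 and BAG1 at −0.59 ± 0.09. Histones were lower for 6 of 13 (7 adjusted over the list alone, adjusted p = 0.466 with an estimated correlation). H2BC5 was at −1.21 ± 0.19. Ribosome biogenesis genes were lower for 10 of 21 (10 adjusted over the list alone, adjusted p = 0.406 with an estimated correlation). RRP12 was at −0.48 ± 0.07. STMN2, a neuronal tubulin-binding protein, was higher (36.6 ± 0.647 CPM against 0.218 ± 0.154 in WT, SD), and NEFM (−7.09 ± 0.14) and ZCCHC12 (−1.63 ± 0.09) were lower. HEK lineage markers were higher for 3 of 9 and lower for 2 (4 and 2 adjusted over the list alone, adjusted p = 0.379 with an estimated correlation), with a median of 0.263 but a mean of −0.524 and a test direction of lower. In all, 5279 of 13606 genes differed (2690 higher, 2589 lower), 5582 and 6563 against each pair of WT columns and 3101 without knock-in library 2.

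Further lists were tested. Interferon response genes rose for 3 of 21 and fell for 3 with arsenite in WT RNA-seq (3 and 3 adjusted over the list alone, adjusted p = 0.798; median −0.002, mean −0.087, test direction higher), and 11 of 18 were lower and 3 higher with eIF2α siRNA (11 and 3 adjusted over the list alone, adjusted p = 0.25). Targets of p53 were higher for 11 of 20 and lower for 4 with eIF2α siRNA in RNA-seq (11 and 4 adjusted over the list alone, adjusted p = 0.381 with an estimated correlation). The cell cycle inhibitor CDKN1A changed by 1.07 ± 0.08 and the apoptosis gene BBC3 by 1.14 ± 0.10. Fibroblast markers were lower for 2 of 4 in double KO RNA-seq (2 adjusted over the list alone, adjusted p = 0.745).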

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

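Of the tests below, the test of exchanged siRNA libraries was chosen only after the result was seen, as were the fits with both lines as 1 group and the limit to splits that keep pairs together.

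The RNA-seq columns of arsenite-treated eIF2A KO cells equal those of untreated eIF2A KO cells in each row. A score over 107 genes that arsenite moved in the other genotypes, 0 for untreated and 1 for treated, was −0.009 to 0.14 for the 4 columns, −0.137 to 0.11 for untreated libraries and 0.813 to 1.10 for treated ones. A mean of 0.054 argues against arsenite-treated libraries under both labels. Untreated libraries under both labels stay open: the highest column, 0.14, lay just above the untreated range, so this test alone does not settle it. No biological explanation was tested.

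EIF2S1 footprints rose with siRNA 2 while its mRNA fell, and the siRNAs differed by 2.04 in log2 (siRNA 2 against siRNA 1). Against an exchange of siRNA 2 and control footprint libraries, ATF4 target genes rose with siRNA 2 by a median of 2.03 (36 of 37 higher). Reads of the transfected siRNA itself may be the source: 1 transcript of EIF2S1 (ENST00000556724.1, 67360353 to 67374648) was at −4.25 (80.3 CPM with control, 4.21 with siRNA 2), while the other transcripts rose by 0.68 to 1.15, so the added counts lie on part of the gene. With siRNA 1 the other transcripts were at −0.82 to −1.25 and this one at 0.20, holding 92.4 of the 102 CPM on the full transcript. A change in the translation of part of the mRNA stays open, as untested.

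Footprints of uORF mRNAs rose less with arsenite in the knockout lines than in WT, with median differences of −0.36, −0.235 and −0.288 in eIF2A KO, eIF2D KO and double KO. In eIF2D KO the list did not pass with an estimated correlation (adjusted p = 0.0524). A weaker arsenite response of all genes may account for it: over 343, 309 and 366 genes that arsenite moved 2-fold or more in the other knockouts, the response was 0.835, 0.869 and 0.796 of that in WT (0.836, 0.87 and 0.796 without the uORF mRNAs), beside 0.732, 0.866 and 0.794 for the uORF mRNAs. In eIF2D KO the ratio was 0.803 in line 1 and 0.921 in line 2, which is above the limit of 0.9 set beforehand, so for that line this explanation stays open. Whether 1 deviating WT library is the cause stays open: without WT library 1 the eIF2D KO difference kept 0.587 of its size. The lowest shares kept in eIF2A KO and double KO were 0.869 and 0.756. A need for eIF2A or eIF2D in this response stays open, as untested.

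The footprint response to arsenite differed from that of WT for 29 genes in eIF2A KO, 117 in eIF2D KO and 179 in double KO. The efficiency response did for 51 in eIF2D KO and 73 in double KO. Among named genes the log2 difference was −1.07 for PPP1R15A in eIF2A KO. In double KO it was −0.51 for ATF4, −0.78 for PPP1R15A, 0.70 for HMOX1 and 1.29 for EIF2D in Ribo-seq. In efficiency it was −0.63 for ATF4 and 1.35 for EIF2D, targeted there and low in footprints. In eIF2D KO it was −1.29 for RPL39 in Ribo-seq and −0.86 for RPL10A in efficiency. With both lines as 1 group each of these calls ended (adjusted p = 0.15 to 1), and with transcripts summed per gene each of those in Ribo-seq did (0.0507 to 0.079). The 1-group fit has no term for the line, so line differences that cancel in a response enter its spread. In double KO Ribo-seq the call of ATF4 ended without each of 10 of the 12 libraries (0.0502 to 0.204), that of PPP1R15A without library 1 or 2 of untreated WT (0.0602 and 0.16) and that of EIF2D without library 1 of untreated or of treated WT (0.0727 and 0.0534). In eIF2A KO that of PPP1R15A ended without library 2 of untreated WT (0.0538), and in eIF2D KO that of RPL39 without it (0.22) or library 2 of untreated line 1 (0.053). The ATF4 call in efficiency ended without each of 3 libraries (footprint library 2 of untreated WT, footprint or RNA-seq library 1 of treated WT, 0.073 to 0.0921).

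Lines of 1 genotype differed from each other in 5567, 4989 and 6244 genes in RNA-seq (eIF2A KO, eIF2D KO, double KO), in 2585, 2193 and 2683 in Ribo-seq and in 6, 13 and 34 in efficiency. The 4 KO and 4 WT RNA-seq libraries of each genotype come as 4 pairs, 1 for each line and for each listed WT pair. The WT pairs had a chi-square per gene of 2.333 and 4.212 within and 17.96 to 22.42 between them, so splits of the 8 libraries into groups of 4 were compared where they keep the pairs together. There are 3 such splits, too few for a share under 0.05. With both lines as 1 group and 8 libraries per fit, 1 of the 3, the real one, gave as many genes: 538, 2837 and 325, against 23, 5 and 121 in the highest other split, which joined the first-listed WT pair with line 2 in eIF2A KO and with line 1 in eIF2D KO and double KO.

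The total of protein-coding counts in WT RNA-seq (18.19 to 37.65 M (M, mega), n = 4) had 1 library apart from the others, with a gap of 0.863 of the range. Chance gives such a gap in about 1 in 20 groups. Mitochondrial rRNA genes, outside the tested genes, held at least 5.40% of counts in arsenite-treated WT Ribo-seq, against 0.663% and 1.30% in untreated WT.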

How the results depend on the processing

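Alternatives chosen only after the data were seen were the transcripts summed per gene, each pair of WT RNA-seq columns alone, the fit without eIF2A KO RNA-seq, and both lines or siRNAs as 1 group. The cause of a change was not tested unless stated. Depth limits which genes have enough counts to be tested: Sel-TCP-seq, with a median of 2.665 M protein-coding counts (M, mega) per library, tested 11265 genes, Ribo-seq of the knockouts and WT 12975 and RNA-seq 14519, with medians of 6.55 M and 25.98 M over all distinct libraries. Counts of changed genes stayed within 1.5 times in 24 of 24 comparisons with RLE factors (ratios 0.857 to 1.235), and in 15 of 24 with DESeq2. They did so 21 of 24 without a filter, 12 of 24 with transcripts summed, 9 of 19 with the compared libraries alone, 6 of 11 with each WT pair, 7 of 8 without eIF2A KO RNA-seq, and 2 of 7 with voom. With fewer lines they did so in 7 of 9 with line 1 alone, 5 of 9 with line 2 alone, 3 of 3 with each siRNA alone and 0 of 17 with lines or siRNAs as 1 group. The median log2 change moved by at most 0.042 with RLE factors, 0.044 with the size factors of DESeq2 and 0.075 without a filter. A replicate block kept 24 of 24 within 1.5 times (ratios 0.902 to 1.444; 4659 genes in eIF2A KO RNA-seq and 38 for the footprint response of eIF2A KO) and ended no call of a named gene, and same-numbered libraries deviated together (correlation over 0.1) in 21 of 66 pairs in RNA-seq and 20 of 91 in Ribo-seq and in 0 of the other 11. The numbers thus do not pair the libraries throughout, but did within some sets: 0.386 to 0.512 in RNA-seq and 0.122 to 0.174 in Ribo-seq in the pairs among treated libraries of the eIF2D KO and double KO lines, 0.239 to 0.346 between treated RNA-seq of WT and 3 of these 4 lines (0.051 with line 1 of eIF2D KO), and 0.152 to 0.218 in those among untreated Ribo-seq libraries of WT, both eIF2A KO lines, line 2 of eIF2D KO and line 1 of double KO. In eIF2A KO against WT Ribo-seq, where each pair was over 0.1, the block gave 981 genes against 910, and in the arsenite response differences 143 and 234 in Ribo-seq and 62 and 78 in efficiency for eIF2D KO and double KO. The planned fits with WT RNA-seq replicates 1 and 2 or 3 and 4 were not run as named, because the columns carry no such numbers. The pairs in order of listing took their place. The efficiency response of eIF2A KO gave no value, since its RNA-seq columns are identical. Taking each gene named in the text under each alternative, 3000 of 3080 results kept their direction and side of the threshold, 70 lost the call, 8 gained it and 2 reversed. The share kept was 196 of 200 with DESeq2, 199 with RLE, 198 without a filter, 200 with the block, 190 with transcripts summed, 1395 of 1416 with 1 library left out and 64 of 97 as 1 group. EIF2S1 footprints with eIF2α siRNA, −0.26 in the mean of both siRNAs, were at 0.072 as 1 group (adjusted p = 0.963) and 0.76 with siRNA 2 alone (1.02e-17), and the call ended with DESeq2 (0.0596), transcripts summed (0.616) and without library 2 of siRNA 2 (0.0648). APC2 efficiency got no adjusted p from DESeq2. List tests past the threshold numbered 175 with the preset correlation, 28 with an estimated one and 230 with fry.

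Counts that moved by over 1.5 times, counts whose share of higher genes shifted by over 10 percentage points, and correlations that moved by more than the spread between single lines follow by setting. With DESeq2 the difference in footprint response was 116 genes in eIF2A KO (24 higher, 92 lower), 197 in eIF2D KO and 431 in double KO. That in efficiency response was 150 in eIF2D KO and 232 in double KO. Efficiency was 40 in eIF2A KO (20 higher, 20 lower) and 394 in eIF2D KO (188 higher, 206 lower). SiRNA Ribo-seq gave 2777, the eIF3D against the eIF3B pulldown 715, and the Ribo-seq correlation of eIF2A KO and eIF2D KO was 0.432. In double KO efficiency DESeq2 called 111 (35 higher, 76 lower). As 1 group, RNA-seq gave 682 (230 higher, 452 lower), 1981 and 473 genes for eIF2A KO, eIF2D KO and double KO. Ribo-seq gave 18 (1 higher, 17 lower), 163 and 6 (0 higher), efficiency 2, 10 and 7 (0 higher in each). With siRNA the counts were 4528, 2306 and 121 in RNA-seq, Ribo-seq and efficiency. The differences in arsenite response were 0, 1 and 0 in Ribo-seq and 0 and 0 in efficiency (edgeR; 629, 516, 695, 508 and 589 at an unadjusted p under 0.05). Line 1 alone gave 8 genes in eIF2A KO efficiency and 1838 in double KO Ribo-seq, with 6 of 69 higher in double KO efficiency. Line 2 alone gave 1933 in eIF2A KO Ribo-seq (794 higher, 1139 lower), 3181 in double KO RNA-seq, and 34 and 84 in efficiency of double KO and eIF2D KO. The first-listed WT pair gave efficiency counts of 332 (181 higher, 151 lower) in eIF2A KO, 743 (345 higher, 398 lower) in eIF2D KO and 473 (236 higher, 237 lower) in double KO. It gave response differences of 234 in eIF2D KO and 336 in double KO, and RNA-seq correlations of 0.620, 0.667 and 0.648. The second-listed pair gave 11, 91, 44, 31 and 41 for the same 5 counts. Voom gave 95 (48 higher, 47 lower), 843 and 313 for efficiency and 6 and 6 (5 higher, 1 lower in double KO) for the response differences. Without a filter the differences in footprint response were 273 (161 higher, 112 lower), 176 and 324. Correlations were 0.468 in RNA-seq for eIF2A KO with eIF2D KO and 0.590, 0.637 and 0.635 in Ribo-seq. The compared libraries alone gave 1554 for arsenite in WT RNA-seq (910 higher, 644 lower). They gave 2625 (1091 higher, 1534 lower), 3478 and 2844 (1129 higher, 1715 lower) in KO Ribo-seq, 31 (17 higher, 14 lower), 346 and 139 (43 higher, 96 lower) in KO efficiency. Response differences were 15 (2 higher, 13 lower) in eIF2A KO and 310 in double KO Ribo-seq and 41 in double KO efficiency. The RNA-seq correlation was 0.335 for eIF2A KO with eIF2D KO. Transcripts summed per gene gave 483, 878 and 338 in KO Ribo-seq, 5 (0 higher), 87 and 40 in KO efficiency. Response differences were 8, 68 and 72 in Ribo-seq. This setting also gave 2832 and 560 for siRNA Ribo-seq and efficiency, 515 for the eIF3D against the eIF3B pulldown. Correlations were 0.487 in RNA-seq and 0.530 in Ribo-seq for eIF2A KO with eIF2D KO and 0.604 in Ribo-seq for eIF2A KO with double KO. Without eIF2A KO RNA-seq the efficiency response of double KO differed for 48 genes, and 19 of 62 genes in double KO efficiency were higher.

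Leaving out 1 library at a time, where a lone library is assumed to vary like the other groups, gave these lowest and highest counts: arsenite in WT 3306 to 3922 in RNA-seq, 3496 to 4002 in Ribo-seq and 3377 to 4605 in efficiency. The RNA-seq counts were 3471 to 4616 in eIF2A KO, 5144 to 5960 in eIF2D KO and 3901 to 4968 in double KO. Those of Ribo-seq were 318 to 645, 658 to 1182 and 232 to 527. For LTM they were 5663 to 6211. For eIF3D they were, against input, 4026 to 4662 and, against eIF3B, 811 to 1416. For the knock-in cells they were 3101 to 5265. For siRNA they were 6968 to 8147 in RNA-seq, 2745 to 4179 in Ribo-seq and 1011 to 1651 in efficiency. Libraries that moved these by over 1.5 times are named in the report. Efficiency was 4 to 40 in eIF2A KO. The counts in brackets are those without WT footprint library 1 (4) or 2 (10), KO footprint libraries 1 and 2 of line 1 (10 and 9) or 2 of line 2 (8), KO RNA-seq library 1 of line 2 (11), or the second-listed WT RNA-seq pair's first (40) or second column (30). In eIF2D KO it was 64 to 355. It moved without WT footprint library 1 (83) or 2 (64), KO footprint library 2 of line 1 (88) or 1 of line 2 (91), KO RNA-seq library 2 of line 1 (103) or of line 2 (112), or the first column of the first-listed (103) or second-listed WT pair (355). In double KO it was 29 to 116. It moved without WT footprint library 1 (30) or 2 (29), KO footprint libraries 1 (53) and 2 (51) of line 1 or 1 of line 2 (44), KO RNA-seq libraries 1 and 2 of line 1 (55 and 50) or of line 2 (49 and 55), or the first-listed WT pair's columns (52 and 53). The difference in footprint response was 4 to 320 in eIF2A KO. The counts in brackets are those without untreated WT library 1 (4) or 2 (8), untreated KO library 2 of line 1 (12) or 1 and 2 of line 2 (12 and 13), treated KO library 2 of line 1 (51) or 1 of line 2 (320). In eIF2D KO it was 33 to 154. It moved without untreated WT library 1 (37) or 2 (33), treated WT library 1 (70) or untreated KO library 2 of line 1 (60). In double KO it was 25 to 209. It moved without untreated WT library 1 (25) or 2 (46), treated WT library 1 (64), untreated KO library 2 of line 1 (113) or 1 and 2 of line 2 (99 and 101), or treated KO library 2 of line 1 (93). The difference in efficiency response was 22 to 102 in eIF2D KO. The counts in brackets are those without untreated WT footprint library 1 (29) or 2 (22), treated WT footprint library 2 (83), treated KO footprint library 1 of line 1 (93) or 2 of line 2 (102), treated WT RNA-seq library 1 (23) or 2 (91), or the second-listed WT pair's columns (79 and 78). In double KO it was 23 to 287. It moved without untreated WT footprint library 1 or 2 (23 each), treated WT footprint library 1 (37) or 2 (132), untreated KO footprint library 2 of line 1 (48) or 1 of line 2 (42), treated KO footprint library 1 of line 2 (123), untreated KO RNA-seq library 1 or 2 of line 1 (48 and 40), treated KO RNA-seq library 1 of line 1 or 2 of line 2 (48 each), or treated WT RNA-seq library 1 (24) or 2 (287).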

Other observations

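The test of where eIF3D-bound fragments lie was chosen only after the shares at transcript ends had been seen.

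The mRNA of NEFM, the medium neurofilament subunit, was at 163 ± 11.7 CPM in WT (SD, n = 4), 2.20 and 5.98 in the eIF2D KO lines, 28.1 ± 2 and 224 ± 2.17 in eIF2A KO lines 1 and 2, 188 and 223 in the double KO lines (n = 2 each) and 1.19 ± 0.411 in the eIF3D-V5 knock-in cells. With siRNA it was at 120 CPM in the control and 58.3 and 117 with eIF2α siRNA 1 and 2.

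RPL39, which encodes a small protein of the large ribosomal subunit, gained footprints with arsenite in WT, where 37 of 80 ribosomal protein mRNAs lost them and 9 gained them. Its footprints were 3.55 ± 1.07 CPM untreated and 106 ± 1.72 with arsenite (SD, n = 2), while its mRNA was at 51.8 ± 5.04 (n = 4) and 57.0 ± 10.8 CPM (n = 2). Its efficiency rose with eIF2α siRNA by 3.47 ± 0.36 (log2 ± SE), where 16 of 77 ribosomal protein mRNAs rose and 15 fell. TDRD5, a gene known for its part in the germline, had 0.294 ± 0.244 CPM of footprints in untreated WT and 45.1 ± 6.97 with arsenite, and 3.26 CPM with CHX and 92.1 with LTM.

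Fragments bound by eIF3D lay near the 5′ ends of mRNAs, with a median of 88.1% of counts on short 5′ transcripts that made up 23.9% of the length, against 59.7% in the 40S input. A candidate explanation is that eIF3D-bound small subunits are held close to the cap or the start codon. The shares had been seen before this was put forward, so they cannot support it, and it stays open. The eIF3B pulldown reached 87.9%, so the share does not set eIF3D apart from another subunit of eIF3. Positions of single reads were not analysed here.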
